A study of Mus musculus with 3 samples.

How the data were processed

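Polyadenylated RNA from 3 samples of bone-marrow-derived macrophages, 1 group by the labels, was analysed from the authors' quantification tables. Replicate numbers come from the labels. Per the labels, each library was made from 1 µg RNA with a size range of 250 to 400. Per the file lists deposited with the samples, all tables use the mouse assembly mm10 and annotation M21. Each sample has a gene table and a transcript table made from a transcriptome alignment, and a second transcript table made from FASTQ files, from 6 files in replicate 1 and 4 each in replicates 2 and 3. The programs and their versions are not given in the sources used here. Nothing in the sources used here says whether counting used strand.

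Per the file headers, the alignment tables hold expected counts and TPM, and the FASTQ tables hold estimated counts and TPM. The deposited transcript tables also give the percent of a gene's TPM in each transcript, which was recomputed here from the TPM values. The gene tables list 81881 entries, of which 55536 matched GENCODE M21 genes by identifier and 26248 have numeric names and 0 counts. Another 96 are ERCC spike-ins with 0 counts, and 1, also named as a spike-in, is the phage phiX174. PhiX, the only one of these with counts that names no mouse gene, took 0.178%, 0.107% and 0.115% of counts in replicates 1, 2 and 3 and was left out of library sizes and tests.

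Total expected counts were 23418690, 36863611 and 37728915, so a count of 0 allows up to 3 counts, or 0.128, 0.0815 and 0.0796 CPM. Intervals and floors cover counting error only. Gene levels are the deposited TPM, averaged over 3 replicates with their SD. Expressed genes have at least 1 TPM in all 3. The level of a list is the median over its members of mean log2(TPM + 1), set among 10000 random lists of the same size from protein-coding genes; this describes these libraries and is no test over samples. The 6 list contrasts compare mean log2(TPM + 1) of members by a two-sided permutation test over genes with 100000 resamples, members of both lists left out, with Benjamini-Hochberg adjustment over 6. Genes are not independent replicates. Gene ratios are log2 of the TPM ratio within a sample, and low-count ratios carry exact (Clopper-Pearson) intervals.

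Expected counts were rounded to whole numbers for edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr and scaled by TMM, with factors of 0.982, 1.03 and 0.992. An intercept-only quasi-likelihood fit gave the biological coefficient of variation and, per gene, an F value of its dispersion over the trended prior (prior degrees of freedom 4.26), tested one-sided and adjusted by Benjamini-Hochberg at 0.05. Library shifts are medians over list members of log2 CPM minus the gene's mean, set among 10000 random lists matched on mean expression in 20 bins, with a smallest possible p of 1e-04, adjusted over 78 values. Sharing of reads was assessed as the percent of a gene's 31-base sequences that occur in transcripts of other GENCODE M21 genes. Of 158 named genes, 32 share at least 10% and 6 at least 50% of these, 44 overlap a gene on the opposite strand and 28 a gene on the same strand; their levels are uncertain to that extent. Other tools were limma 3.58.1, DESeq2 1.42.0 for size factors, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

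The 3 tests were run on simulated data. With dispersions on the trend, the excess-variance test recovered 1%, 93% and 100% of 200 genes changed 2-, 4- and 8-fold in a single library among 11813, 11797 and 11813 genes. A simulation added after the count of 0 was seen scattered dispersions around the trend by the prior degrees of freedom of these data. There the test recovered 0% at each size among 11698, 11698 and 11688 genes. Its data were noisier, with a common coefficient of variation of 0.262 at 2-fold, against 0.201 with dispersions on the trend and 0.197 in these data. The list contrast passed in 6%, 64.5% and 100% of 200 runs with shifts of 0, 2 and 4 between lists of 20 genes. The list shift test, on libraries of independent noise, passed for 0%, 100% and 100% of 10 lists at shifts of 0, 0.5 and 1. Shifts of 0.5 and 1 put into a single library appeared on average as 0.316 and 0.642 from the mean of the replicates. Members of real lists vary together, so the 0% does not carry over to them, and smaller shifts were not simulated.

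The gene lists, contrasts, ratios, the rule for named genes and all alternatives other than those named as later were chosen before the data were examined. The lists are TLR4 receptor and adaptors, negative regulators of TLR signalling, stimulus-responsive transcription factors, immediate early genes, cytokines, chemokines, interferon-stimulated genes, antigen presentation and costimulation, antimicrobial effectors, pattern recognition receptors, inflammasome and cell death, alternative activation, sterol metabolism and LXR, glycolysis, TCA cycle and respiration, redox and iron, lysosome and autophagy, cell cycle and long noncoding RNAs. Beside these stand 12 cell type lists and an isoform list of 25 genes, 2 of which have a single annotated transcript. Named genes are the 25 most abundant nuclear protein-coding genes, the 3 highest members of each list, in the 5 lists of cytokines, chemokines, interferon-stimulated genes, antimicrobial effectors and negative regulators also the 6 highest and every member below 1 TPM in all replicates, the genes of the 10 ratios, the 10 genes of lowest excess-variance p with a mean of at least 5 TPM, the isoform list, Xist and 4 Y-linked genes. Families named in the closing section were chosen after their values were seen, and are called so there. Single values of 2 of the named genes are not reported here.

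The alternatives were thresholds of 0.5 and 5 TPM or 10 counts, the FASTQ tables, TPM scaled to nuclear protein-coding genes, a pseudocount of 0.1 for 1, medians for means, members of at least 1 TPM, expressed genes as background, counts not divided by length, DESeq2's size factors, no filter on low counts, a mean count of at least 50, a prior that is not robust, limma-voom, shares of TPM for shares of counts, and leaving out each replicate. FASTQ tables scaled to protein-coding genes, removal of a GC content and length trend and thinning to the depth of replicate 1 were added after seeing the data. Signal tracks and alignments were not used here, and no comparison between groups was made because the labels give a single group.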

Results

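Polyadenylated RNA was measured in macrophages grown from the bone marrow of C57BL/6J mice, an inbred laboratory strain. Per the labels, the cells were exposed to 100 ng/ml lipid A for 12 hours, kept without it for 12 hours after a wash, and exposed to 100 ng/ml lipid A again for 180 minutes. Lipid A is the membrane anchor of bacterial lipopolysaccharide and a ligand of Toll-like receptor 4 (TLR4). Other label fields name the agent as lipoprotein A, of type protein; the conflict is left as the labels give it. The 3 samples form a single group of replicates 1, 2 and 3, and all carry the same donor record. P-values of the excess-variance test therefore measure only the spread between these samples, which may be technical, and those of the permutation tests measure the spread between genes. Exposure, washout and renewed exposure is a layout used to study how an earlier stimulus alters a later response. Cells left unexposed or exposed once were not analysed here, so levels, comparisons between gene groups within the cells, and the spread between replicates are reported. Total expected counts were 23418690, 36863611 and 37728915 in replicates 1, 2 and 3. Gene levels are TPM, given as mean ± SD over n = 3 replicates.

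Fth1, which encodes the ferritin heavy chain, stood highest among nuclear protein-coding genes at 56509 ± 12507 TPM (SD, n = 3). It was followed by the T cell and monocyte attractant Ccl5 at 24721 ± 3140.3 TPM and the acute-phase gene Saa3 at 19258 ± 3213 TPM. The ferritin light chain gene Ftl1 was at 17481 ± 1203 TPM, the actin-sequestering Tmsb4x at 15294 ± 3091 TPM, the class I light chain gene B2m at 15036 ± 1260.3 TPM and the lysozyme gene Lyz2 at 10782 ± 581 TPM. Lysosomal genes were also abundant, with Psap at 8729 ± 789.7 TPM, Ctsb at 7859 ± 750.4 TPM and Ctsd at 7034 ± 741 TPM. Apoe, which carries lipids, was at 4995 ± 2656 TPM, with 2924, 7989 and 4072 TPM in replicates 1, 2 and 3. The number of expressed genes, those with at least 1 TPM in all 3 replicates, was 10510, of which 9749 were protein coding. The 10 most abundant genes took 12.5% ± 0.849 of counts and the 100 most abundant 31.9% ± 0.749; of TPM they took 20.6% and 43.6%. Ftl1 shares 64.2% of its 31-base sequences with other genes, mainly its pseudogene Ftl1-ps1, so its level is uncertain.

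Macrophage markers were high and markers of other blood, stromal and endothelial cells were mostly near the detection limit. All 20 macrophage genes reached 1 TPM in every replicate, and 17 of them had a mean of at least 100 TPM. Examples are Lyz2, the transmembrane glycoprotein gene Gpnmb at 5084 ± 1422 TPM (SD, n = 3) and the complement gene C1qb at 2899 ± 409.5 TPM. Their median log2(TPM + 1) was 9.44 ± 0.13, at or above that of all 10000 random lists of protein-coding genes of the same size. The monocyte list had a median of 2.06 ± 0.48, at the 76.6 percentile of these lists and the 0.52 percentile of lists drawn from expressed genes, with Plac8 at 78.7 ± 9.91 TPM and Ly6c2 at 31.7 ± 4.68 TPM.

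**Figure D1:**
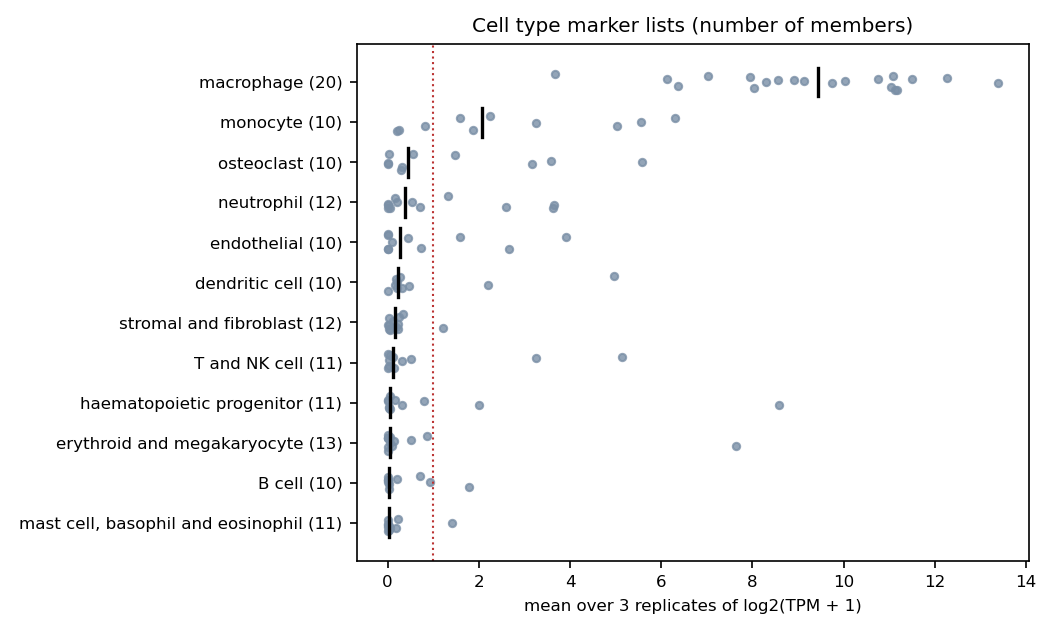
Levels of 12 cell type marker lists. Each point is a gene, placed at its mean log2(TPM + 1) over 3 replicates, black bars are list medians, and the dotted line marks 1 TPM; the macrophage list has a median of 9.44 and the other lists have medians of 2.06 or lower.

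The remaining cell type lists had medians below 1 TPM. At least 1 TPM in all replicates was reached by 3 of 12 neutrophil, 2 of 10 dendritic cell, 1 of 11 mast cell, basophil and eosinophil, 1 of 10 B cell and 2 of 11 T and NK cell genes. The counts were 1 of 13 for erythroid and megakaryocyte, 0 of 12 for stromal and fibroblast, 3 of 10 for endothelial, 2 of 11 for haematopoietic progenitor and 3 of 10 for osteoclast genes. Their medians stood between the 21.2 and 44.6 percentiles of the random lists, and below all lists of expressed genes. Single members stood out from their lists. The platelet factor gene Pf4 was at 208 ± 84.4 TPM (SD, n = 3), the surface protein gene Ly6a at 409 ± 171 TPM, the T cell coreceptor gene Cd4 at 36.7 ± 14.7 TPM, the bone-resorbing phosphatase gene Acp5 at 47.9 ± 12.4 TPM, the actin-bundling Fscn1 at 30.6 ± 5.70 TPM and the growth factor receptor gene Kdr at 15.8 ± 8.12 TPM. The calprotectin genes S100a8 and S100a9, which neutrophils express strongly, were at 6.84, 39.4 and 5.36 TPM and 4.2, 58.0 and 5.10 TPM in replicates 1, 2 and 3.

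Chemokine transcripts were abundant, led by Ccl5 (ENSMUSG00000035042.2, chromosome 11, 83525778 to 83530518, minus strand; coordinates are of the mouse build GRCm38, which the files call mm10). The interferon-induced T cell attractant Cxcl10 was at 3904 ± 389 TPM (SD, n = 3), and the monocyte attractants Ccl4, Ccl3, Ccl7 and Ccl2 were at 2496 ± 574, 2029 ± 706, 1389.9 ± 469 and 964 ± 531 TPM. Neutrophil attractants were lower, with Cxcl2 at 135 ± 145 TPM, Cxcl1 at 18.9 ± 15.5 TPM and Cxcl5 at 0.0567 ± 0.0603 TPM, and the Th2-type chemokine gene Ccl17 was at 0.163 ± 0.165 TPM. Of the chemokine genes, 18 of 21 reached 1 TPM in all replicates, and the list's median of 7.14 ± 0.52 was at or above that of all 10000 random lists.

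Among cytokines, Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007, minus strand), an early inflammatory cytokine, was highest at 983 ± 252 TPM (SD, n = 3), with 27927, 30866 and 28619 counts. The interleukin 1 genes Il1b and Il1a were at 494 ± 91.1 and 436 ± 126 TPM, and the interleukin 27 subunits Ebi3 and Il27 at 306 ± 38.7 and 158 ± 25.5 TPM. Il15, which sustains natural killer cells, was at 237 ± 5.36 TPM. Il6 (ENSMUSG00000025746.11, chromosome 5, 30013114 to 30019981, plus strand) stood at 159, 16.4 and 45.4 TPM in replicates 1, 2 and 3, and Il12b, the shared subunit of interleukins 12 and 23, at 69.8, 50.4 and 175 TPM. The anti-inflammatory Il10 was at 18.6 ± 4.66 TPM, and Lif stayed below 1 TPM in every replicate. In all, 15 of 20 cytokine genes reached 1 TPM, with a list median of 5.16 ± 0.72, at or above all 10000 random lists and at the 97.65 percentile among expressed genes. The cytokine list lay below the chemokine list by a mean of -1.77 ± 0.15 on the log2(TPM + 1) scale, lower in each replicate. The difference did not pass the permutation test over genes (two-sided p = 0.136, adjusted p = 0.204 over 6 contrasts); genes of a list are not independent replicates.

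**Figure D2:**
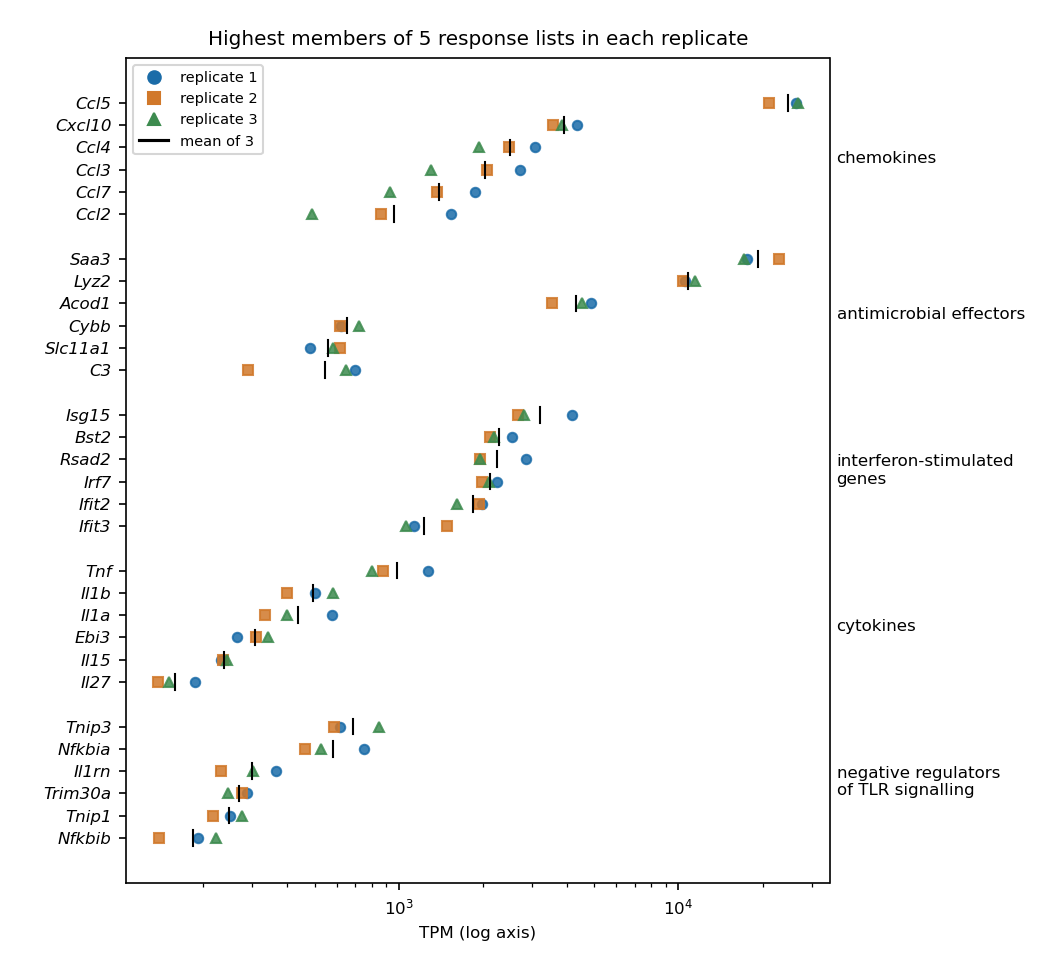
TPM of the 6 most abundant members of 5 response lists on a log axis. Symbols are the 3 replicates and black bars are their means; Ccl5 and Saa3 lie highest, with means of 24721 and 19258 TPM.

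Interferon-stimulated genes were high as a group. All 31 reached 1 TPM in every replicate, 28 had a mean of at least 100 TPM, and the list's median was 9.10 ± 0.05 (SD, n = 3), at or above all 10000 random lists. The ubiquitin-like modifier gene Isg15 was at 3209 ± 815 TPM, the virus-tethering Bst2 at 2279.8 ± 219.8 TPM, the antiviral enzyme gene Rsad2 at 2251 ± 519.6 TPM and the interferon regulatory factor gene Irf7 at 2116 ± 131 TPM. Ifit2 and Ifit3, which bind viral RNA, were at 1841 ± 201 and 1229 ± 230.2 TPM. The list lay above the cytokine list by 3.98 ± 0.26 in mean log2(TPM + 1), and by 3.71 to 4.23 in each replicate. The permutation test over genes gave a two-sided p = 1e-05, the smallest that 100000 resamples can give (adjusted p = 6e-05). Ifit3 shares 61.8% of its 31-base sequences with Ifit3b, so how its reads divide is uncertain.

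Antimicrobial effector genes stood far above genes of alternative activation, the programme that interleukin 4 induces. Saa3 (ENSMUSG00000040026.8, chromosome 7, 46711998 to 46715700, minus strand), Lyz2 and Acod1 (ENSMUSG00000022126.6, chromosome 14, 103046977 to 103056573, plus strand), the enzyme that makes itaconate, led the effectors, with Acod1 at 4308 ± 708 TPM (SD, n = 3). The oxidase subunit gene Cybb was at 653 ± 57.3 TPM, the phagosomal metal transporter gene Slc11a1 at 560.2 ± 69.7 TPM and the complement gene C3 at 544 ± 222 TPM. Nos2, the inducible nitric oxide synthase gene, was at 69.2 ± 33.4 TPM and the prostaglandin synthase gene Ptgs2 at 86.2 ± 49.7 TPM. Camp, Mmp9 and Ptx3 stayed below 1 TPM in every replicate. The effector list had a median of 7.82 ± 0.33 and 19 of 22 members at 1 TPM or more. Of the alternative activation genes 10 of 17 reached 1 TPM, led by the interleukin 4 receptor gene Il4ra at 79.7 ± 8.47 TPM, the scavenger receptor gene Stab1 at 74.8 ± 33.6 TPM and the folate receptor gene Folr2 at 28.1 ± 10.1 TPM. That list's median was 1.90 ± 0.24, at the 78.7 percentile of protein-coding lists and the 0.03 percentile of lists drawn from expressed genes. The lists differed by 4.44 ± 0.27, in the same direction in all 3 replicates (permutation test over genes, two-sided p = 0.00028, adjusted p = 0.00056).

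Feedback inhibitors of TLR signalling were transcribed alongside the receptor machinery. Tnip3, which binds the ubiquitin editor A20, was at 684 ± 142 TPM (SD, n = 3), Nfkbia, the main inhibitor of NF-kappaB, at 580.0 ± 151 TPM and the interleukin 1 receptor antagonist gene Il1rn at 299 ± 66.7 TPM. Trim30a, Tnip1 and Nfkbib were at 269 ± 21.9, 247 ± 29.6 and 184 ± 41.8 TPM, while Sigirr and Il1rl1 stayed below 1 TPM in every replicate. The list had 22 of 24 members at 1 TPM or more and a median of 5.96 ± 0.03, at or above all 10000 random lists. Of the receptor and adaptor genes 20 of 21 reached 1 TPM, with a median of 4.91 ± 0.23 at the 99.97 percentile, or the 93.9 percentile among expressed genes. The lipopolysaccharide coreceptor gene Cd14 was at 474, 390.2 and 982 TPM in replicates 1, 2 and 3, the adaptor gene Myd88 at 164 ± 19.7 TPM, the kinase gene Irak2 at 141 ± 3.28 TPM and Tlr4 itself at 18.4 ± 4.46 TPM. The regulators lay above the receptor genes by 0.72 ± 0.12, which did not pass the permutation test over genes (two-sided p = 0.266, adjusted p = 0.319). With only members at a mean of at least 1 TPM, the difference was 1.22 and passed (permutation test, adjusted p = 0.0464). That setting leaves out Sigirr and Il1rl1, the 2 regulators below 1 TPM in every replicate, against 0 such receptor genes. Dropping the lowest regulators raises the difference by construction, so the pass is no separate support.

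Stimulus-responsive transcription factors were more abundant than immediate early genes. Besides Irf7, the interferon regulatory factor gene Irf1 was at 323 ± 26.4 TPM (SD, n = 3), and all 24 factors reached 1 TPM in every replicate. Among immediate early genes, the stress-induced repressor gene Atf3 was at 303 ± 3.67 TPM, Junb at 177 ± 35.3 TPM and Zfp36, which destabilises cytokine messages, at 82.8 ± 22.4 TPM, and 12 of 16 reached 1 TPM. The list medians were 6.56 ± 0.09 and 3.83 ± 0.39. The former was at or above all 10000 random lists, and the latter was at the 98.5 percentile, or the 41.3 percentile among expressed genes. Without Atf3 and Junb, the 2 genes in both lists, the factors lay higher by 3.31 ± 0.16, in all 3 replicates (permutation test over genes, two-sided p = 0.0001, adjusted p = 0.0003). These 2 are the highest immediate early genes, so leaving them out widens the difference.

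Genes of glycolysis and of respiration were both well expressed. Gapdh was at 1357 ± 206 TPM (SD, n = 3), Aldoa, whose 2 gene identifiers were summed, at 538 ± 66.6 TPM and Pkm at 449 ± 48.6 TPM, and 16 of 16 glycolysis genes reached 1 TPM. The ATP synthase gene Atp5b was at 618 ± 30.7 TPM and the cytochrome oxidase genes Cox5a and Cox4i1 at 586 ± 32.3 and 495 ± 55.1 TPM, and 20 of 21 genes of the TCA cycle and respiration reached 1 TPM. The list medians were 7.25 ± 0.10 and 6.34 ± 0.06. The mean difference of 0.69 ± 0.22 did not pass the permutation test over genes (two-sided p = 0.345, adjusted p = 0.345).

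Other gene groups ranked high as well. The antigen presentation and costimulation list had a median of 7.74 ± 0.29 (SD, n = 3), led by B2m and the class I heavy chain genes H2-K1 at 8606 ± 396 TPM and H2-D1 at 4924 ± 263 TPM. Lysosome and autophagy genes had a median of 8.76 ± 0.13, with the protease gene Ctss at 4219 ± 97.7 TPM. Pattern recognition receptors had a median of 6.54 ± 0.17, led by the C-type lectin gene Clec4e at 1677 ± 466 TPM and Cd14, followed by the lectin gene Clec4d at 388 ± 17.5 TPM. The inflammasome and cell death list had a median of 6.54 ± 0.20, with the nucleic acid sensor gene Zbp1 at 531 ± 35.6 TPM and Casp1, which processes interleukin 1 beta, at 302 ± 57.0 TPM. Sterol metabolism genes had a median of 5.44 ± 0.08, led by the LXR alpha gene Nr1h3 at 143 ± 49.0 TPM and the cholesterol exporter genes Abcg1 at 91.3 ± 12.2 TPM and Abca1 at 86.7 ± 18.4 TPM. Redox and iron genes had a median of 5.74 ± 0.49, with the peroxide-reducing Prdx1 at 1676 ± 278 TPM. These 6 medians lay at or above the 99.97 percentile of protein-coding lists and the 98.8 percentile of lists of expressed genes.

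Cell cycle genes were the lowest response list apart from alternative activation. Their median was 2.70 ± 0.23 (SD, n = 3), at the 91.7 percentile of protein-coding lists and the 1.25 percentile among expressed genes, and 12 of 20 reached 1 TPM. The replication clamp gene Pcna was at 224 ± 29.5 TPM, the helicase gene Mcm6 at 24.0 ± 4.202 TPM and the proliferation marker Mki67 at 19.3 ± 7.72 TPM. Long noncoding RNAs had a median of 4.29 ± 0.41, at the 98.8 percentile of protein-coding lists and the 65.7 percentile among expressed genes, with Malat1 at 511 ± 76.9 TPM, Neat1 at 274, 224 and 70.5 TPM in replicates 1, 2 and 3, and Gas5 at 169.7 ± 38.3 TPM.

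Ratios within each sample set opposing or related genes side by side. Tnf exceeded Il10 by a log2 ratio of 5.72 ± 0.57 (SD, n = 3) and Cxcl10 exceeded the neutrophil attractant Cxcl1 by 8.04 ± 1.12. Il6 stood below Tnf, with a log2 ratio of -4.29 ± 1.38, and Il10 below Il12b, with -2.22 ± 1.20. The receptor antagonist Il1rn stood below its agonist Il1b at -0.73 ± 0.25, the monocyte marker Ly6c2 below the macrophage marker Adgre1 at -6.14 ± 0.51, and Tlr2, the lipoprotein receptor gene, above Tlr4 at 3.97 ± 0.73. Nfkbia exceeded Tnfaip3, the gene of A20, by 1.73 ± 0.16. All 3 replicates lay on the same side of 0 in each of these 8 ratios, and an exact two-sided sign-flip test of 3 values cannot give p below 0.25. Arg1, the arginase gene of alternative activation, had 0, 0 and 2 counts in replicates 1, 2 and 3 against 5424, 3109 and 9320 for Nos2, a count ratio of Nos2 to Arg1 of 8926.5 (exact 95% interval 2471 to 73715). Il23a had 23, 0 and 9 counts against 1781, 2068 and 7286 for Il12b, a ratio of Il12b to Il23a of 348 (exact 95% interval 246 to 509). Without replicate 1 the ratio of Il12b to Il23a was 1039 and without replicate 3 it was 167, and without replicate 3 that of Nos2 to Arg1 was at least 2844, with the floor of 3 counts. The intervals cover counting error only, and the count ratios are not divided by length. Without division by length, Nfkbia exceeded Tnfaip3 by only 0.29, and Il1rn stood below Il1b by -0.13, with replicate 1 on the other side (9392 counts for Il1rn, 8751 for Il1b).

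The replicates correlated closely across genes, and no gene passed the test for excess variance. The common biological coefficient of variation was 0.197, and its trend ran from 0.311 in the least to 0.160 in the most abundant genes. Across genes, which are not independent replicates, Pearson correlations of log2(TPM + 1) were 0.985, 0.986 and 0.988 for replicates 1 and 2, 1 and 3, and 2 and 3. A chi-square test of counts gave 65.8, 67.5 and 63.5 per degree of freedom for these pairs, so no table is a copy of another; separately made libraries exceed counting noise in any case. Of 11992 genes tested with edgeR's quasi-likelihood fit (one-sided), 0 passed a Benjamini-Hochberg adjusted p of 0.05. An unadjusted p under 0.05 was found for 648, where a share of 0.05 would be 599.6, and limma-voom gave 0 and 649. The prior is fitted to the spread of these same genes, so a number near 599.6 follows largely from the fit and is no evidence against excess variance. The genes with the lowest p, none past the threshold (adjusted p = 0.753 in edgeR), included Il6, the neutrophil attractant Cxcl2 at 302, 53.8 and 47.7 TPM in replicates 1, 2 and 3, and the stress cytokine gene Gdf15 at 162, 30.4 and 23.4 TPM. The others were the cystine transporter gene Slc7a11 at 9.32, 1.27 and 7.67 TPM, Slfn4 at 254.8, 107 and 34.5 TPM, the lipase gene Lipg at 38.0, 6.39 and 31 TPM and Herpud1, a gene of endoplasmic reticulum stress, at 55.8, 18.2 and 12.6 TPM. Zfp36l1 was at 8.26, 23.9 and 3.57 TPM, mt-Co2 at 504, 66.2 and 104.8 TPM and Gm26778 at 8.40, 4.16 and 76.4 TPM. The last 3 share 60.0%, 100% and 99.3% of their 31-base sequences with other genes, so their levels are uncertain. In simulations the test recovered 100% of genes changed 8-fold in a single library with dispersions on the trend, and 0% with dispersions scattered around it. The scattered data were noisier than the real ones, so the power here is not known and the count of 0 says little about single genes. Without a filter on low counts, the count was 474 of 20285.

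Gene groups moved together between replicates. Of 78 shifts over 26 lists, 38 passed the test against matched random lists (resampling, two-sided, adjusted p under 0.05). A gene's shifts cancel out over the replicates, so those of a list are not independent of each other, and some genes are in several lists. Of the 38, 19 kept their call and stayed within 1.5 times their size under every alternative that gave a value. Among these 19, cytokine genes were higher in replicate 1, with a median log2 shift from the mean of the replicates of 0.32. They were lower in replicate 2 at -0.32 (test against matched random lists, adjusted p = 0.00065 for each). Replicate 1 was also higher in long noncoding RNAs at 0.39, immediate early genes at 0.29, redox and iron genes at 0.29, interferon-stimulated genes at 0.18, glycolysis at 0.12 and transcription factors at 0.10, and lower in cell cycle genes at -0.26 and macrophage markers at -0.14. In replicate 2, cell cycle genes at 0.45 and macrophage markers at 0.12 were higher, while glycolysis at -0.20 and progenitor markers at -0.78 were lower. The progenitor value rests on the 3 of 11 listed markers that had enough counts, and thinning left too few of them for a value. In replicate 3, the same 3 progenitor markers were higher at 0.49. Long noncoding RNAs at -0.53, immediate early genes at -0.28, chemokines at -0.18 and interferon-stimulated genes at -0.07 were lower there. Interferon-stimulated genes were at -0.07 in replicate 2 as well, without passing (test against matched random lists, adjusted p = 0.249). The calls differ because matched random lists had medians of 0.05 in replicate 3 and -0.03 in replicate 2. The 3 neutrophil markers with enough counts were higher in replicate 2, at 1.71 (1.13 in the FASTQ tables), and lower in replicates 1 and 3, at -0.63 and -1.09 (-0.41 and -0.72). Of the 38, 10 lost their call under at least 1 alternative and 9 kept it with a size that moved by over 1.5 times; members of a list vary together, so all are differences between libraries of a single condition.

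**Figure D3:**
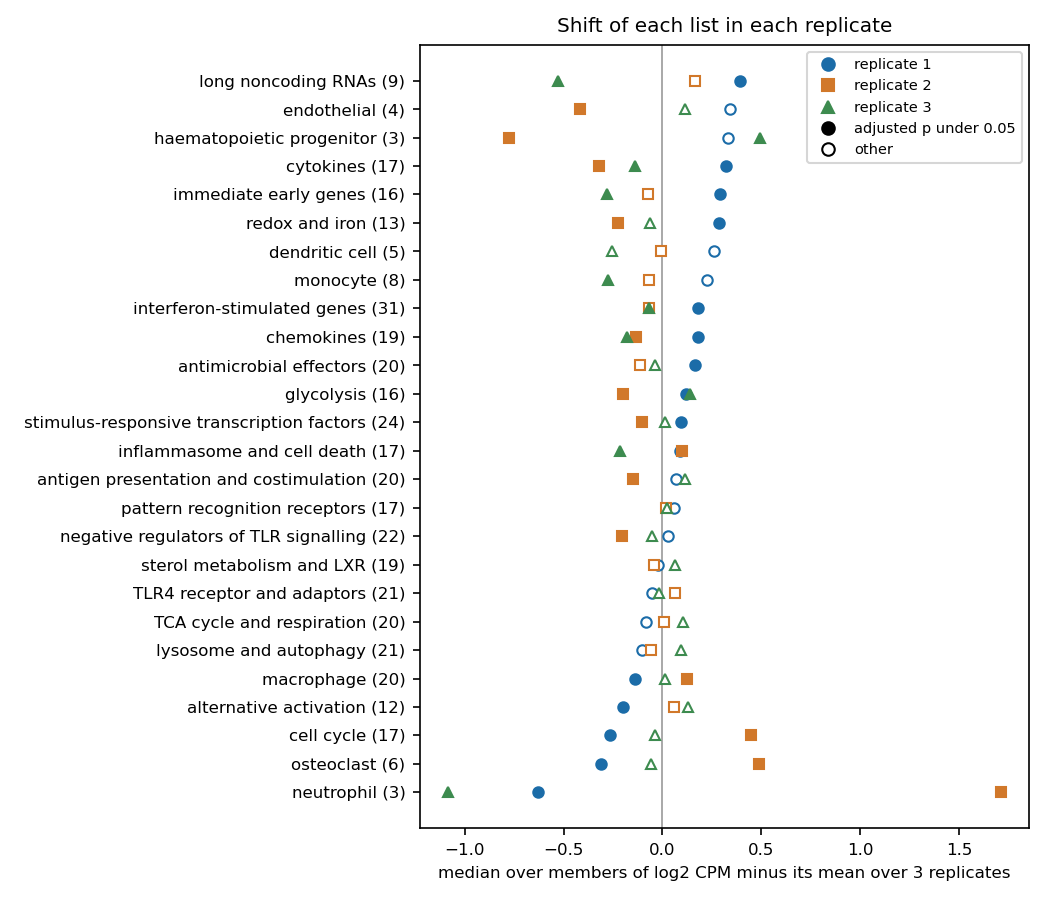
Median shift of each gene list in each replicate, as log2 CPM minus the gene's mean over 3 replicates. Filled symbols passed against random lists at an adjusted p under 0.05, open symbols did not, and numbers of members are in brackets; the neutrophil markers in replicate 2 lie farthest out, at 1.71.

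Some response genes used almost a single protein-coding transcript and others were divided among several. Of 23 genes with several annotated transcripts, 7 had over 90% of their TPM in the most abundant transcript. For Tnf-201 (chromosome 17, 35199381 to 35202007) the share was 99.9% ± 0.0552 (SD, n = 3), for Nos2-201 99.9% ± 0.1001, for Ptgs2-201 99.9% ± 0.242, for Il1b-201 99.5% ± 0.201, for Myd88-201 98.8% ± 0.514, for Tlr4-201 97.4% ± 0.658 and for Cxcl10-201 96.9% ± 0.843. Zbp1-202 held 56.9% ± 1.81 and Zbp1-201 40.9% ± 1.11, Tnfaip3-201 held 47.3% ± 3.93 and Il15-202 43.5% ± 3.29. Pkm-201 held 72.9% ± 3.16 and the antagonist transcript Il1rn-201 77.0% ± 2.19. The most abundant transcript was the same in the second table, made from FASTQ files, in 21 of the 23 genes and differed for Cd44 and Ptprc. For Csf1r, the macrophage growth factor receptor gene, Csf1r-201 held 74.6% ± 5.77 in the alignment table and 96.0% ± 2.65 in the FASTQ table.

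**Figure D4:**
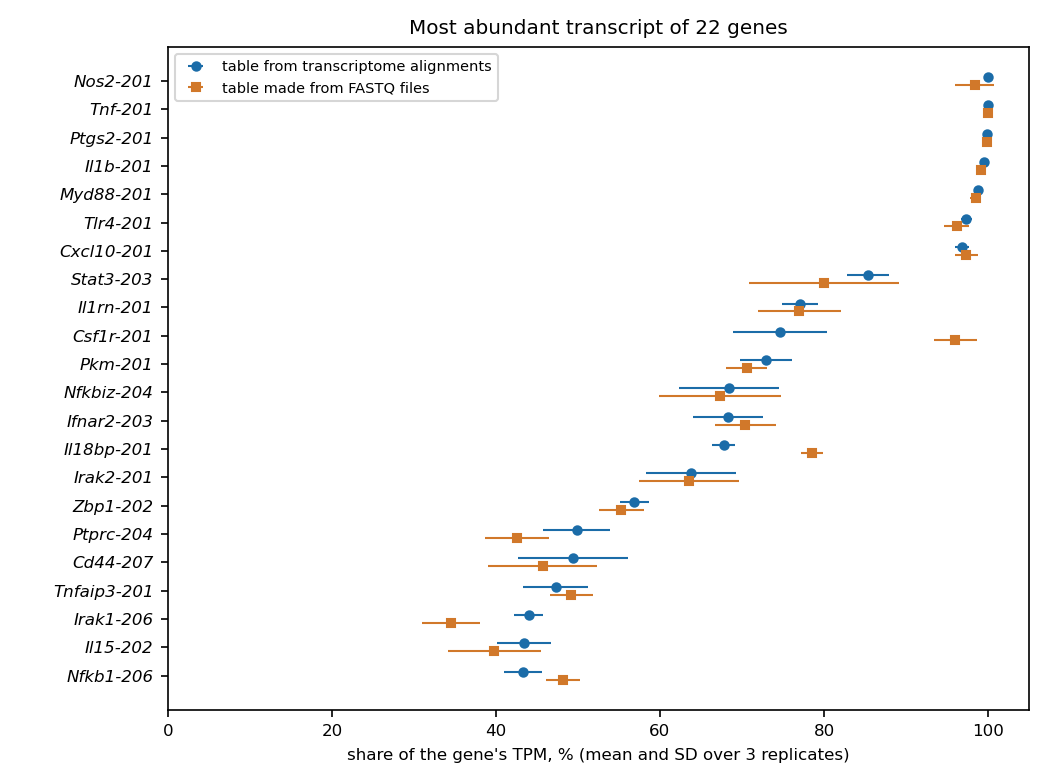
Share of each gene's TPM in its most abundant transcript, in percent, for 22 of the 23 genes with several annotated transcripts; 1 is not shown. Points are means and bars SDs over 3 replicates, in each of 2 quantification tables; Csf1r-201 lies at 74.6% in the alignment table and 96.0% in the FASTQ table.

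The levels of most protein-coding genes were close in the 2 quantifications. Among protein-coding genes at 1 TPM or more in the alignment table, 98.7% ± 0.0242 (SD, n = 3) lay within 2-fold after both tables were scaled to nuclear protein-coding genes. Genes that reached 1 TPM only in the FASTQ table are left out of this share. Over all measured features, the Pearson correlation of log2(TPM + 1) was 0.923 ± 0.0108 across transcripts and 0.959 ± 0.00648 across gene sums. Counted reads in the alignment tables came to 76.3%, 90.9% and 92.2% of those in the FASTQ tables in replicates 1, 2 and 3.

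The composition of the libraries was alike in most respects. Mitochondrially encoded genes took 1.29% ± 0.152 of counts (SD, n = 3) and ribosomal protein genes 1.39% ± 0.0685; of TPM, which divides by length, they took 3.67% ± 0.873 and 4.99% ± 0.353. Haemoglobin genes had 1.43e-06% ± 2.47e-06. A ribosomal RNA gene, CT010467.1, took 2.77%, 2.37% and 1.37% in replicates 1, 2 and 3. The mitochondrial share holds only reads assigned to the mitochondrial genes themselves, so it may be too low. The gene mt-Co2, at 504.5, 66.2 and 104.8 TPM in replicates 1, 2 and 3, shares 99.5% of its sequences with the nuclear Gm28661. Gm28661 was listed at 4773, 8248 and 7149 TPM. In replicate 2, mt-Atp6 had 893 counts in the alignment table and 43630 in the FASTQ table. For mt-Co1 these were 280182 and 316934. The size of any shortfall was not computed. Xist, the RNA that silences an X chromosome in female cells, was at 65.4, 65.6 and 35.9 TPM, and the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were at 0 in all 3 replicates; the labels give the sex as not collected.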

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

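No test was run on the values in this part. Counts of the phage phiX174, which is no mouse sequence and enters none of the comparisons, were 41599, 39505 and 43203 in replicates 1, 2 and 3. They stand out as a signal outside the main measurement, above the 3 counts that a count of 0 allows. The gene tables name this entry as a spike-in, like those of ERCC. No control samples were analysed here. The alignment tables hold 86.8%, 90.2% and 90.8% of the phiX counts of the FASTQ tables.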

How the results depend on the processing

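The FASTQ tables scaled to protein-coding genes, the removal of a GC content and length trend and the thinning were chosen after the data were seen. No contrast changed direction, nor did any of the 38 shifts of lists past the threshold; of the 40 other shifts, 11 changed sign under at least 1 alternative. The antimicrobial, interferon-stimulated gene and transcription factor contrasts kept their direction and side of the threshold under every alternative, with ranges of 4.004 to 5.92, 3.20 to 4.37 and 2.32 to 3.69. Of 42 contrast values under alternatives, 41 kept their side. The exception was negative regulators minus TLR4 receptor and adaptors, at 1.22 with members of at least 1 TPM, against adjusted p from 0.264 to 0.446 otherwise (permutation test over genes). That setting leaves out 2 regulators near 0, which raises the difference by construction. Counts not divided by length gave log2 ratios of -0.13 for Il1rn to Il1b, -8.28 for Ly6c2 to Adgre1 and 0.29 for Nfkbia to Tnfaip3, a change that comes from transcript length by construction. These are 3 of the 16 ratio values that could move by 1 SD, since leaving out 1 of 3 replicates cannot move a mean that far; leaving out a replicate took Il6 to Tnf from -4.94 to -3.57, Il10 to Il12b from -2.80 to -1.60 and Cxcl10 to Cxcl1 from 7.49 to 8.61.

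The count of excess-variance genes was 0 with DESeq2's size factors, a mean count of at least 50, a prior that is not robust, limma-voom, the FASTQ tables and without each replicate, with 566 to 741 genes at an unadjusted p under 0.05. Without a filter on low counts edgeR called 474, of which 405 are in genes the filter keeps; its prior degrees of freedom then became infinite, against 4.26, so each gene's own spread was tested against a fixed trend. Restricting the comparison of the quantifications to features of at least 1 TPM in either table gave correlations of 0.862 across transcripts and 0.912 across genes, since features low in both tables drop out.

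Of 188 shifts of lists under alternatives, 173 stayed past the threshold and 15 did not; the cause was not tested. For 2 shifts of the haematopoietic progenitor list, thinning left too few members for a value. Of 948 gene levels under alternatives, 814 moved by less than 1 SD; 474 of the 948 come from leaving out a replicate, which cannot move a mean of 3 that far, so they say nothing of stability. Of the 134 others, 64 moved in the FASTQ tables, 56 of them down. Protein-coding genes took 75.7%, 76.6% and 86.7% of TPM there in replicates 1, 2 and 3. In the alignment tables they took 93.2%, 92.8% and 93.9%, so lower TPM in the FASTQ tables follows in part from scaling. Another 39 moved with scaling to protein-coding genes, all up by construction. The other 31 moved with both, 10 of them to below the unscaled level. Shares of TPM for shares of counts moved 5 of 6 classes, all up. Of 186 list percentiles 29 moved, 16 with expressed genes as background. Of 25 isoform shares 11 moved in the FASTQ tables, the only alternative able to move them by 1 SD. Depth limits the genes near 0, and 3 replicates limit any test of a single gene.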

Other observations

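The families in this paragraph were chosen after their values were seen. In several families of interferon-inducible genes, most or all genes searched for reached 1 TPM in every replicate, against 9749 of 22028 protein-coding genes. All 10 guanylate-binding protein genes found by name reached 1 TPM in every replicate, with a summed level of 2538 ± 80.8 TPM (SD, n = 3), led by Gbp2 at 980.1 ± 22.1 TPM and Gbp5 at 589 ± 71.3 TPM; these proteins attack vacuoles that hold pathogens. All 7 p47 GTPase genes searched for did so too, with a sum of 2074 ± 202 TPM and Irgm1 highest at 539 ± 31.6 TPM. That search was by chosen names and need not cover the family. Of 13 PYHIN genes, a family of nucleic acid sensors, 12 reached 1 TPM, with Ifi211 at 1050.3 ± 63.3 TPM and Ifi205 at 1030.0 ± 222 TPM. Of 8 Schlafen genes 7 did, and Slfn2 at 1853 ± 302 TPM stood far above Slfn5 at 336 ± 16.1 TPM. The Ms4a cluster of membrane protein genes had the largest sum of these 5 families, 7415 ± 423 TPM, with Ms4a4c at 2816 ± 38.6 TPM and Ms4a6c at 1369.5 ± 97.6 TPM, while 8 of its 19 genes reached 1 TPM. Members of a gene family can be close in sequence. Sharing of sequences was not computed for the genes named in this paragraph, so how reads divide among them is uncertain.

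Gm26778 (chromosome 14, 102978220 to 102982528) lies within Kctd12 on the opposite strand (102976581 to 102982637), and the pair share 99.3% of the sequences of Gm26778. Gm26778 was at 8.40, 4.16 and 76.4 TPM in replicates 1, 2 and 3 and Kctd12 at 251, 294 and 277 TPM. The mitochondrial gene mt-Co2 shares 99.5% of its sequences with the nuclear copy Gm28661 on chromosome 1, which was listed at 4773, 8248 and 7149 TPM against 504, 66.2 and 104.8 TPM for mt-Co2.

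In the FASTQ table of replicate 1, the test on repeated bases having been chosen after the result was seen, the transcript Klf10-204 (chromosome 15, 38299874 to 38300706, minus strand, 326 bases) held 330752 counts, against 4474 and 4304 in replicates 2 and 3. In the alignment tables the gene Klf10 had 216, 588 and 339 counts and 4.87, 8.47 and 4.97 TPM. No annotated ribosomal or mitochondrial transcript shares a 31-base sequence with Klf10-204 (0 found), and its longest match to the Illumina adapters tried is 8 bases. This argues against annotated ribosomal or mitochondrial RNA and against those adapters as the source. Ribosomal sequence outside the annotation was not searched and stays possible. Reads of a single repeated base are a candidate explanation: the transcript holds a run of 33 A, and 166 other transcripts with a run of 31 A or T (43 more had under 10 counts) had a median log2 ratio of replicate 1 to the others of 1.47 in the FASTQ tables, above all 10000 random lists (highest 0.319), with 142 of 166 higher, against 0 in the alignment tables; yet the summed share of all 209 in the FASTQ counts was only 1.26 times that of the other replicates, far less than the rise of Klf10-204. No biological explanation was tested.

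The cytokine list was higher in replicate 1, with a median shift of 0.32 over 17 members, 13 of them above their mean; the intervals given here, over resampled members, were no part of the rule set beforehand, by which a share kept of 0.75 or more argues against an explanation. Thinning the other libraries to the depth of replicate 1 kept 0.975 of the shift (0.978 to 1.006, where the value averages 20 draws and the interval resamples their mean). Thinning leaves each gene's expected share of reads unchanged, so it bears only on the noise of lower counts, and argues against that alone. With genes filtered again, 2 members dropped out and the shift was 0.27. Removing a GC content and length trend kept 0.948 (0.222 to 1.11) and the FASTQ tables kept 0.899 (0.476 to 1.005), which by that rule argues against either, but the wide intervals leave a contribution possible. Intervals of the members' median change, computed after those were seen, are narrower (0.792 to 0.974 and 0.901 to 0.946), and no conclusion is drawn from them. No biological explanation was tested.

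S100a8 and S100a9 were higher in replicate 2, by 6.45 and 12.5 times the mean of the others, and the form of the test on granulocyte markers was chosen after the values were seen. The mean log2 shift of the pair kept 0.997 of its value after removal of a GC content and length trend. The trend took only 0.533% of variance in replicate 2, so its removal could hardly change a shift of 2.02. This argues only against a smooth trend of that size. Granulocytes in replicate 2 were a candidate source; the tally of markers highest there, 8 of 12 where the rule set for the test asked for 9, decides nothing, since it includes the pair itself and Cxcr2 on a single count. By that rule a low Camp, 1.94 times the others, beside a high Ngp, 23.2 times the others, argues against granulocytes (odds ratio of Ngp to Camp 10.7, exact 95% interval 3.36 to 34.2), but Camp had only 6, 12 and 3 counts and another granule gene of the list, Ltf, rose with Ngp at 3, 53 and 0 counts, so the question was left open, a choice made after the counts were seen. No biological explanation was tested.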
